A study of Saccharomyces cerevisiae with 312 samples.

How the data were processed

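Chromatin endogenous cleavage sequencing (ChEC-seq) was done in budding yeast strains that carry Msn2 fused to MNase, with variants of the disordered region of Msn2, grown in synthetic complete medium with glucose to an optical density of 4, per the labels. Of 312 samples, 311 have a file, and the sample FWY_to_N replicate 4 is not analysed here. They form 139 groups: 137 designs (10 with 1 library, 101 with 2, 13 with 3, 12 with 4 and 1 with 5), the wild type MSN2WT with 5 libraries and a second wild type, wt, with 2. Samples were grouped by the genotype in the labels. Replicates may be technical, since the labels do not say what a replicate repeats. The labels use amino acid letters; reading p and n as positive and negative, and rep, x2, x3, to, from and nextto as written, follows the names alone.

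The deposited files hold raw counts per base of the yeast genome, build R64, with 12157105 lines and 1 column each. Bcl2fastq, cutadapt, Bowtie2 and bedtools are named in the labels with no version. All values are whole numbers, the 311 totals are all even, as they would be if both ends of each fragment were counted, and no file repeats another (311 distinct files). The lowest chi-square per degree of freedom between replicates was 1.9 over 233 pairs (median 6.06). The chromosome order within the files was settled from the signal over genes and checked at marker genes. Library totals ranged from 21102 to 32960018 (median 2118678) and the mitochondrial share from 0.0018 to 97.1% (median 4.93%). Counts in the analysed promoters ranged from 4663 to 13416747 (median 494600), with 96 libraries under 200000. Reads are amplified without molecular tags, so counting intervals and floors cover counting error only.

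Promoters were taken as up to 700 bp upstream of each open reading frame, ended at the next one, and joined where they overlapped. Of 6002 nuclear protein-coding genes 78 were dropped for overlap and 5924 kept, giving 4418 promoters after leaving out 4 beside marker genes or MSN2. Then 17 promoters within 2000 bp of the ribosomal RNA repeats and 4 of known Aro80 targets were left out, because the repeats draw a large share of nuclear reads and because libraries of letters A and E carry a strong signal at the Aro80 targets. Both exclusions were decided after looking at the data, before any test was run. The 4397 promoters analysed (3042 with 1 gene, 1355 shared by 2; median 451 bp; 2138587 bp in all) were summed per library. Where 1 promoter serves 2 genes both names are given, and the reads cannot be assigned to either.

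Similarity to wild type is Pearson r over promoters between the RPM (counts per 1000000 promoter counts) of a library and the mean of the MSN2WT libraries, with a MSN2WT library set against the mean of the others. The target share is the percent of promoter reads at the 50 promoters of the stress reporter and the trehalose and glycogen lists. Groups of libraries or designs were compared by exact permutation of means, pairs by exact sign flips and series by permutation of all pairings, with Benjamini-Hochberg adjustment over the 9 design tests; each design counts as 1 value. Promoters were compared between MSN2WT and 9 designs with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling and filterByExpr, and called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. The SE of a log2 fold change is its size over the square root of F. All comparisons share the MSN2WT libraries, so no overlap between them is given. Gene lists from general knowledge of yeast were fixed before the data were examined: stress reporters (30 genes), trehalose and glycogen (21), chaperones (22), oxidative stress (23), glycolysis (22), hexose transport (21), protein kinase A and stress signalling (20), respiration (26), ribosomal proteins (137), ribosome biogenesis (29), mating (22) and galactose (6). A list enters as the promoters of its genes, of which 13 of the 30 for stress reporters and 7 of the 20 for trehalose and glycogen are shared with a neighbouring gene. These 12 lists were tested with fry and camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Groups of libraries were also compared with DESeq2 1.42.0; other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

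The promoters named were fixed by rule. In LIVFWY_deletion they are the 10 largest decreases and 10 largest increases among called promoters where every library of the design lies beyond every MSN2WT library, and in the other comparisons 3 and 3. The 13 promoters of HSP12, CTT1, HSP26, DDR2, TPS1, TPS2, TSL1, PGM2, GPH1, HSP104, SSA4, HXK1 and ALD3 are always included, and gene groups name 2 to 4 members with the largest absolute change. Designs named are those of the planned series and the 5 lowest and 5 highest.

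Data were simulated with the means of MSN2WT and the spread of LIVFWY_deletion against MSN2WT (3799 promoters). There edgeR called 97.7% of 4-fold and 38.9% of 2-fold changes, with 1 false call among 3623. Only 90 promoters were changed 2-fold and 86 4-fold, in both directions, whereas 2360 of 4390 were called in the real comparison. The simulation therefore does not measure errors under so broad a shift. For LIV_deletion, with 2 libraries (4123 promoters), it called 88.4% of 4-fold and 41.1% of 2-fold changes, with 2 false calls among 3933.

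The sample records fall into 2 runs, called block 1 (207 libraries, with MSN2WT) and block 2 (104 libraries, with wt). Comparisons of designs were repeated within the larger block where both hold designs. The replicate numbers do not pair a variant with MSN2WT: r between residuals of equal number lay between -0.167 and 0.078. The alternatives were library size alone, DESeq2 size factors, no filter, promoters of at most 400 bp, each base capped at a high percentile, libraries thinned to 200000 promoter reads, log or rank similarity, wt as the reference or joined to it, a replicate block, and leaving out each library or design. Added later were keeping the promoters beside the ribosomal RNA repeats, keeping the Aro80 targets, leaving out the libraries of letters A and E, and fitting the libraries with shared replicate numbers without the block. The preference for the Msn2 sequence motif was planned but not computed, since no genome sequence was at hand.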

Results

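Msn2 is a budding yeast activator of general stress genes. In these strains it is fused to micrococcal nuclease (MNase), so DNA ends gather beside the sites it occupies. With the unaltered protein (MSN2WT), promoters of trehalose and glycogen genes such as TPS2 and TSL1 were among those with the most reads. HXK1, encoding a hexokinase (chromosome VI, 255050 to 255749), led with 17581 ± 1376 RPM (counts per 1000000 promoter counts; SD, n = 5 libraries). TPS2, encoding trehalose-phosphate phosphatase (chromosome IV, 593193 to 593892), held 16295 ± 1459, TSL1, a subunit of the trehalose synthase complex (chromosome XIII, 70312 to 70623), 13585 ± 2545, and HOR7, a stress-induced membrane protein gene (chromosome XIII, 774052 to 774751), 11122 ± 569 RPM (SD, n = 5 each). The 100 strongest promoters of each MSN2WT library took 43.2% of its promoter reads on average (41.2 to 45.1%). Each MSN2WT library was correlated over 4397 promoters with the mean of the other 4, and this similarity to wild type was 0.991 ± 0.0031 (SD, n = 5). A separate wild-type group, wt, had a similarity of 0.970 ± 0.021 (SD, n = 2), and 47 of 4171 promoters were called different from MSN2WT in edgeR, 33 lower and 14 higher. At an unadjusted edgeR p under 0.05 there were 782. With 2 wt libraries many differences can be missed, so the few calls do not show that both wild types are alike. The wt library of replicate 2 held 73744 counts in all, so wt serves only as an alternative reference.

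**Figure D1:**
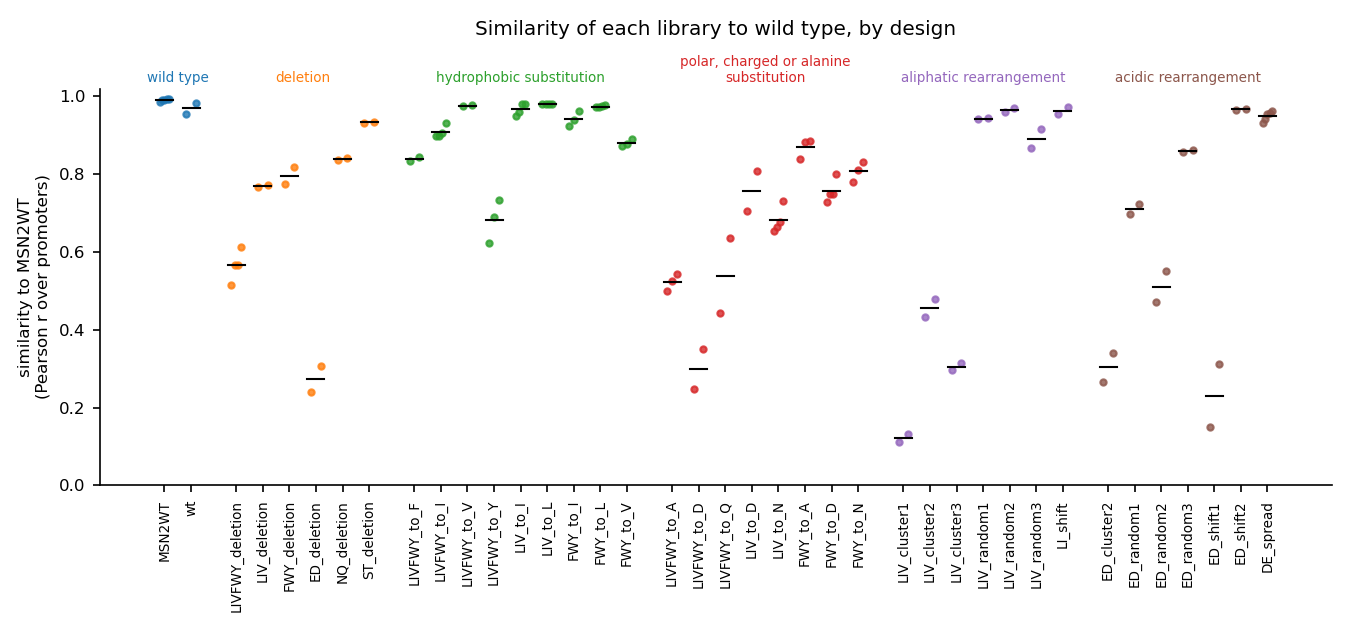
Similarity to MSN2WT (vertical axis, Pearson r over promoters, no unit) of each library (points) and design means (bars), by family of designs (horizontal axis). Hydrophobic substitutions lie higher than polar, charged or alanine substitutions (means 0.906 and 0.654), and clustered aliphatic designs lie far below randomly placed ones (LIV_cluster1 0.123, LIV_random1 0.943).

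Without the hydrophobic residues of its disordered region, reads of the Msn2 fusion were far less like the wild-type pattern over promoters. The label LIVFWY_deletion names leucine, isoleucine, valine, phenylalanine, tryptophan and tyrosine, and asks whether these residues guide promoter choice. Textbook Msn2 target promoters, the general stress and the trehalose and glycogen genes, kept a smaller share of promoter reads. A smaller share of nuclear reads lay in promoters too, and a larger share of all reads was mitochondrial (values in the last paragraph). For both shares a difference between the blocks is not told apart from the deletion. Reads were spread over more promoters, with 13.5% of them at the 100 strongest promoters of each LIVFWY_deletion library against 43.2% in MSN2WT. Similarity to wild type was 0.565 ± 0.040 (SD, n = 4) in LIVFWY_deletion and 0.991 ± 0.0031 (SD, n = 5) in MSN2WT, a difference of -0.426 (-0.237 with the promoters beside the ribosomal RNA repeats kept, -0.210 on the log scale and -0.199 by rank). It was lower in 4 of 4 libraries, with an exact permutation p of 0.00794, the smallest possible for 4 against 5 libraries, and 0.0179 after adjustment over the 9 design tests. That p is not particular to this design, since the reference is the MSN2WT mean itself. Even the highest design mean, 0.985 in PG_shift, lay below the lowest MSN2WT library (0.986). With the 2 wt libraries as reference, which belong to neither group, the exact permutation p stayed under 0.05. The target share was 4.69 ± 0.31% (SD, n = 4) against 17.2 ± 1.0% (SD, n = 5), a difference of -12.5 percentage points (exact permutation p 0.00794, adjusted 0.0179, lower in 4 of 4). MSN2WT and LIVFWY_deletion come from separate runs of sample records, block 1 and block 2, but the wt libraries, which lie in block 2 with LIVFWY_deletion, had similarities of 0.955 and 0.984 to MSN2WT. Against wt the target share difference was -10.8 percentage points (exact permutation p 0.0667, the smallest possible for 4 against 2).

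Among single promoters, those of HOR7 and HXK1 fell most in LIVFWY_deletion. HOR7 held 503 ± 143 RPM (SD, n = 4) in place of 11122 ± 569 (SD, n = 5), and HXK1 1493 ± 225 in place of 17581 ± 1376. Also among the 10 largest decreases were the promoters of HXT7 (a hexose transporter), DIP5 (an amino acid permease), ZWF1 (glucose-6-phosphate dehydrogenase), TPS2, the regulator genes GIS1 and USV1, YDR344C and DDR2. The 10 largest increases lay at promoters nearly free of reads in the wild type, among them EMA35, MSH5, MSH1, PRM7 and NUC1, whose MSN2WT reads summed over 5 libraries ranged from 4 to 36. With trimmed mean of M values (TMM) scaling, edgeR called 2360 of 4390 promoters, 1037 lower and 1323 higher (511 and 521 against wt, 481 and 2496 with MSN2WT and wt joined as the reference). The log2 fold changes were -6.24 (SE 0.21, adjusted p 3.5e-17) at HOR7, -5.35 (SE 0.17, adjusted p 3.4e-17) at HXK1 and -4.97 (SE 0.16, adjusted p 3.5e-17) at DDR2, and 5.12 (SE 0.60, adjusted p 6.6e-08) at EMA35. Of the 13 promoters named in advance, all were called lower, from -5.35 at HXK1 to -1.05 at SSA4, but SSA4 turned higher (0.74) when scaled by library size alone. That scaling moves the median promoter from 0.24 to 2.03 on the log2 scale and the calls to 278 lower and 3193 higher, so every fold change is relative to the bulk of promoters. HXT6 and HXT7 are near-identical copies, and how reads were shared between such copies is unknown.

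**Figure D2:**
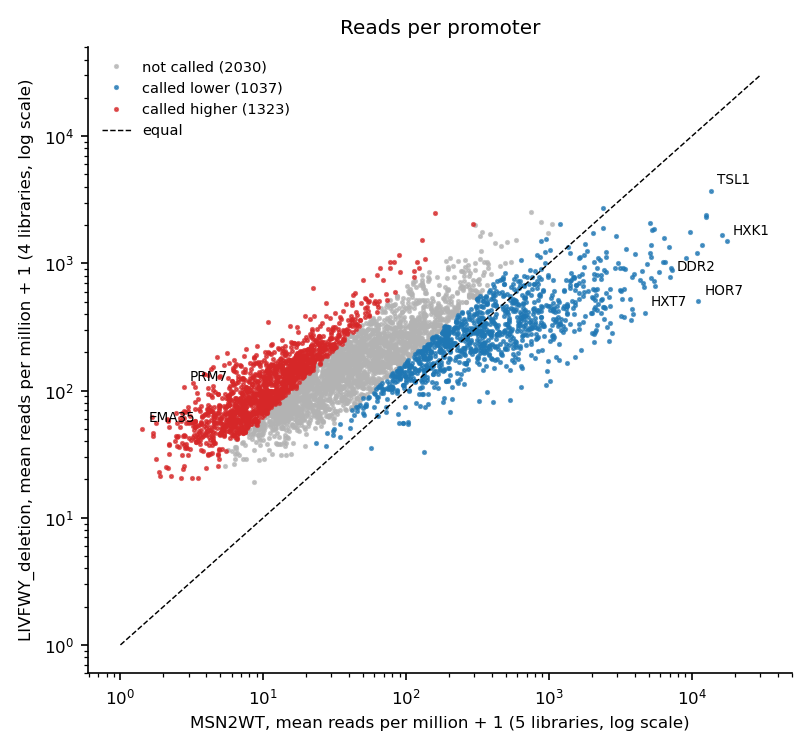
Mean RPM plus 1 per promoter in MSN2WT (horizontal axis, log scale, 5 libraries) and LIVFWY_deletion (vertical axis, log scale, 4 libraries), coloured by edgeR call. HXK1 and HOR7 fall far below the line of equal reads, while the bulk of weak promoters lies above it.

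Gene groups moved apart in LIVFWY_deletion. Stress reporter genes fell at 28 of 30 promoters (median log2 fold change -2.81; HOR7, USV1 and DDR2 led) and trehalose and glycogen genes at 17 of 20 (median -3.15; TPS2, GIP2 and GSY1). Glycolysis genes fell at 17 of 21 (median -2.04; HXK1, TDH3 and HXK2) and protein kinase A signalling genes at 13 of 19 (median -1.81; GIS1, RAS2 and MSN4). By library size alone the medians of these 4 lists were -1.01 (15 lower, 2 higher), -1.36 (12 lower, 3 higher), -0.25 (7 lower, 4 higher) and -0.019 (6 lower, 6 higher), so the last pair of decreases depends on the scaling. Ribosome biogenesis promoters went the other way, with 12 of 28 called higher and 0 lower (median 0.90; 2.69 by library size alone), among them RPA49/CRS1 (2.78) and RPA43/RPA190 (2.38). These 2 promoters were nearly empty in MSN2WT (1.77 and 8.67 RPM), and 1323 of all 4390 promoters were called higher. A rise from a low wild-type level was not told apart from a change of this group. Chaperone genes were called lower at 15 of 22 promoters and higher at 1 (median -1.37), oxidative stress genes at 12 and 1 of 22 (-1.04), hexose transport genes at 9 and 1 of 21 (-0.88) and respiration genes at 12 and 1 of 25 (-0.88), but all 4 medians turn positive by library size alone (0.43, 0.76, 0.91 and 0.90). Ribosomal protein promoters split into 28 lower and 23 higher of 130 (median -0.03; 1.76 by library size alone), mating genes into 6 lower and 8 higher of 22 (median 0.68), and of 5 galactose promoters none passed both thresholds (median 0.05, mean -0.01). These counts are for TMM scaling, since by library size alone the calls over all promoters were 278 lower and 3193 higher. Limma's camera with its preset correlation gave adjusted p values of 9.9e-12 for stress reporters, 1.7e-08 for trehalose and glycogen and 0.00229 for ribosome biogenesis. Over all 9 comparisons it called 79 of 108 list tests, and fry called 87. With an estimated correlation camera called 0 (31 at an unadjusted p under 0.05), and the lowest adjusted p = 0.113 with an estimated correlation. For every list in LIVFWY_deletion the counts were identical when adjusted over the list alone.

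**Figure D3:**
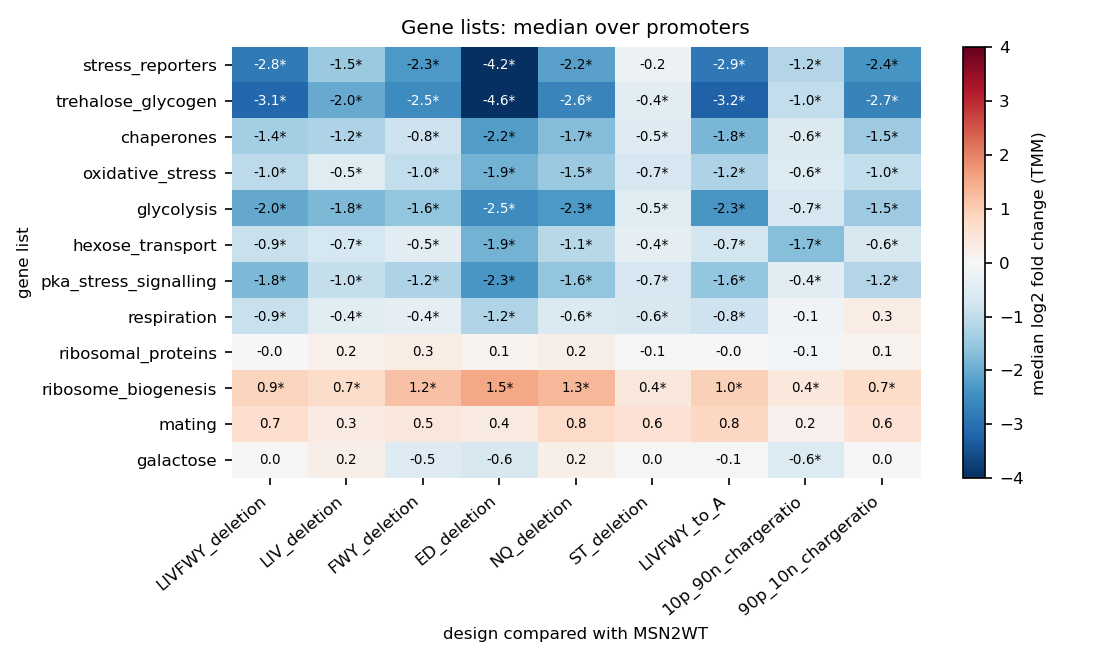
Median log2 fold change over the promoters of each gene list (vertical axis) in each design compared with MSN2WT (horizontal axis), with TMM scaling and an asterisk where camera with its preset correlation gave an adjusted p under 0.05 (79 of 108 list tests; 0 with an estimated correlation). The stress reporter median is below 0 in every design, but in ST_deletion (-0.23; 0.20 by library size alone) without a mark, and hexose transport genes fell furthest in ED_deletion (-1.88; -0.059 by library size alone) and 10p_90n_chargeratio (-1.71; -0.93 by library size alone).

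Deleting single residue classes gave a range of outcomes. Removing serines and threonines (ST_deletion) left most stress reporter promoters uncalled with TMM scaling. YFL015C/HSP12 was called higher (log2 fold change 1.11, SE 0.20, adjusted p 0.000391 in edgeR). In RPM, 7 of the 13 promoters named in advance lay above every MSN2WT library and 1 below. The largest losses were at CTR1 (-3.53, SE 0.89), RSB1 (-2.62, SE 0.19) and YCR022C (-2.51, SE 0.18). CTR1 varied widely among the MSN2WT libraries, from 78.4 to 848 RPM. Removing glutamates and aspartates (ED_deletion) lowered DDR2 by -6.43 (SE 0.36), PGM2/YMR105W-A by -6.38 (SE 0.30) and HXK1 by -6.25 (SE 0.31). Removing aliphatic residues (LIV_deletion) or aromatic ones (FWY_deletion) brought HOR7 down most (-5.34, SE 0.19, and -4.67, SE 0.23), followed by HXT7 (-4.42 and -4.54). In NQ_deletion HOR7 changed by -4.07 (SE 0.20) and IXR1 by -4.57 (SE 0.35). The small heat shock gene HSP26 fell in ED_deletion (-5.75, SE 0.43), NQ_deletion (-3.89, SE 0.21), LIV_deletion (-3.78, SE 0.18) and FWY_deletion (-3.61, SE 0.21), and the catalase gene CTT1 by less in the same order of designs (-4.33, -1.64, -2.54 and -2.84). HSP26 and CTT1 were not called in ST_deletion, though in RPM both lay above every MSN2WT library (1.31-fold and 2.11-fold). Similarity to wild type was 0.933 ± 0.0034 in ST_deletion, 0.839 ± 0.0052 in NQ_deletion, 0.796 ± 0.031 in FWY_deletion, 0.770 ± 0.0030 in LIV_deletion and 0.274 ± 0.048 in ED_deletion (SD, n = 2 each). On the log scale the order of the middle designs turned, with 0.890 in LIV_deletion, 0.810 in FWY_deletion and 0.693 in NQ_deletion (0.899, 0.828 and 0.704 by rank). NQ_deletion had the fewest promoter reads of these middle designs, and a shallow wt library was also low on the log scale. Whether depth accounts for the turn was not tested. The share of nuclear reads in promoters, 50.0 ± 1.9% in MSN2WT (SD, n = 5), was 39.7 ± 1.9% in ST_deletion, 30.2 ± 0.42% in LIV_deletion, 28.1 ± 0.31% in FWY_deletion, 24.6 ± 3.0% in NQ_deletion and 16.9 ± 1.1% in ED_deletion (SD, n = 2 each). In edgeR 376 promoters were called lower and 837 higher in ST_deletion, 791 and 660 in LIV_deletion, 862 and 1127 in FWY_deletion, 1017 and 1325 in NQ_deletion, and 1140 and 1346 in ED_deletion (1461 and 1093 without its replicate B). Each of these 5 designs has a library of letter A, with 1.21 to 10.5% of promoter reads at the Aro80 targets left out of every comparison. Stress reporters were called lower at 7 of 30 promoters in ST_deletion (2 higher; camera adjusted p 0.0694), 21 in LIV_deletion, 26 in FWY_deletion, 27 in NQ_deletion and 28 in ED_deletion. By library size alone the lower and higher counts were 0 and 5 in ST_deletion, 12 and 2 in LIV_deletion (median from -1.47 to -0.099), 13 and 1 in FWY_deletion, 12 and 2 in NQ_deletion and 22 and 2 in ED_deletion, and against wt 0 and 9, 10 and 2, 10 and 0, 9 and 0, and 14 and 0 in the same order.

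Some of the strongest fitted decreases in these deletions rest on no or very few reads. In ED_deletion BUB3 had 0 reads over 2 libraries, at least 6.34-fold lower than MSN2WT with a floor of 3 counts over the group. TRE1/SPT14 had 0 as well (at least 1.98-fold lower), and RDS2/COX11 had 1 read, 85.0-fold lower with a counting interval of 15.2 to 3358. In NQ_deletion STP22/VMA9 had 0 reads (at least 1.65-fold lower), and YPL119C-A is listed at 0 with the floor above its wild-type level. TMA64/APC4 in FWY_deletion had 2 reads, 9.0-fold lower (2.43 to 75.3). If both ends of each fragment were counted, counts are not independent, and these bounds and intervals are too tight. The ED_deletion libraries held 65231 and 437560 promoter reads.

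Designs that replaced hydrophobic residues by other hydrophobic residues were more like wild type than those with polar, charged or alanine residues instead. By their labels, designs such as LIV_to_L leave the residues that already match unchanged, while the other set changes every residue of its class. Taken whole, the sets thus also differ in how many residues were altered, and the pooled comparison does not separate the 2. FWY_to_I, FWY_to_L and FWY_to_V change every residue of their class, as FWY_to_A, FWY_to_D and FWY_to_N do. Those designs were not tested on their own. LIV_to_L (0.981 ± 0.00084; SD, n = 4), LIVFWY_to_V (0.976 ± 0.0014; SD, n = 2) and FWY_to_L (0.974 ± 0.0019; SD, n = 4) were nearest to wild type among the designs of this comparison, and LIVFWY_to_D (0.300 ± 0.073; SD, n = 2) was farthest. The place of FWY_to_L holds only for Pearson r on RPM, since it was the lowest hydrophobic design on the log scale (0.831) and by rank (0.799). On RPM LIVFWY_to_Y was the lowest hydrophobic design (0.682 ± 0.057; SD, n = 3) and FWY_to_A the highest of the other set (0.869 ± 0.026; SD, n = 3), while L_to_A, an alanine design not part of the comparison, lay higher (0.915 ± 0.0056; SD, n = 2). The means over designs were 0.906 ± 0.097 (SD, n = 9) and 0.654 ± 0.188 (SD, n = 8), a difference of 0.252 with an exact permutation p of 0.00197 (adjusted 0.0178). It was 0.0998 (exact permutation p 0.0183) with the promoters beside the ribosomal RNA repeats kept, and 0.282 (exact permutation p 0.000874) within block 2, where all designs but FWY_to_A lie. The alanine design LIVFWY_to_A had a similarity of 0.522 ± 0.023 (SD, n = 3), with its largest decreases at HOR7 (-6.20, SE 0.35), MEP1/YGR121W-A (-5.40, SE 0.28) and HXT7 (-5.33, SE 0.24). In edgeR 2200 of 4319 promoters were called there, 1010 lower and 1190 higher, with 28 of 30 stress reporters lower (16 by library size alone, 14 against wt). EMA35 (5.01), MSH1 (4.38) and PAC2 (4.10) rose most, from at most 22 reads summed over the MSN2WT libraries.

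Over the 9 designs labelled with positive and negative percentages, those with more positive residues tended to be less like wild type. The designs with 10, 20 and 30% positive residues stayed at 0.967, 0.981 and 0.984 mean similarity, those with 40, 50 and 60% at 0.940, 0.749 and 0.818, and those with 70, 80 and 90% at 0.704 ± 0.098 (SD, n = 2), 0.607 ± 0.0057 (SD, n = 2) and 0.829 ± 0.0096 (SD, n = 3). In 90p_10n_chargeratio the largest decreases were at YFL015C/HSP12 (-4.46, SE 0.22), HOR7 (-4.03, SE 0.14) and EGO4 (-3.83, SE 0.16), and the largest increases at EMA35, MSH1 and MSH5 (3.59, 3.36 and 3.06). Those increases started from 4, 11 and 10 reads summed over the MSN2WT libraries, and the lowest library of the design held 1, 5 and 4 reads there. In 10p_90n_chargeratio, with a profile close to wild type, YPR148C (-3.02), YDR344C (-2.84) and MAN2 (-2.73) fell most and PRP45 (2.6), SAW1 (2.42) and DPI35 (2.40) rose most, the last 3 from 104, 30 and 16 summed MSN2WT reads. Hexose transporter promoters were lower there at 17 of 21 and higher at 1 with TMM scaling (median -1.71). HXT6 stood at -2.35, YNR071C/HXT17 at -2.20, HXT7 at -2.17 and HXT3 at -1.95. By library size alone 8 were lower and 1 higher (median -0.93). Pearson r of similarity with the positive percentage was -0.790 (permutation p over exact pairings 0.0136, adjusted 0.0246), Spearman rho was -0.75 (exact p 0.0255), and without the designs at both ends r was -0.943 over 7 designs. In edgeR 740 of 4366 promoters were called in 10p_90n_chargeratio (410 lower, 330 higher; 186 higher when either library of the design is left out) and 1619 of 4370 in 90p_10n_chargeratio (792 lower, 827 higher), with 17 and 27 of 30 stress reporters lower (5 and 14 by library size alone, 2 and 10 against wt). All 9 designs lie in block 1. No library of the 50, 70 and 80% designs holds 200000 promoter reads, and over the designs that remain with libraries thinned to that depth r was -0.896 (exact permutation p 0.0222).

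**Figure D4:**
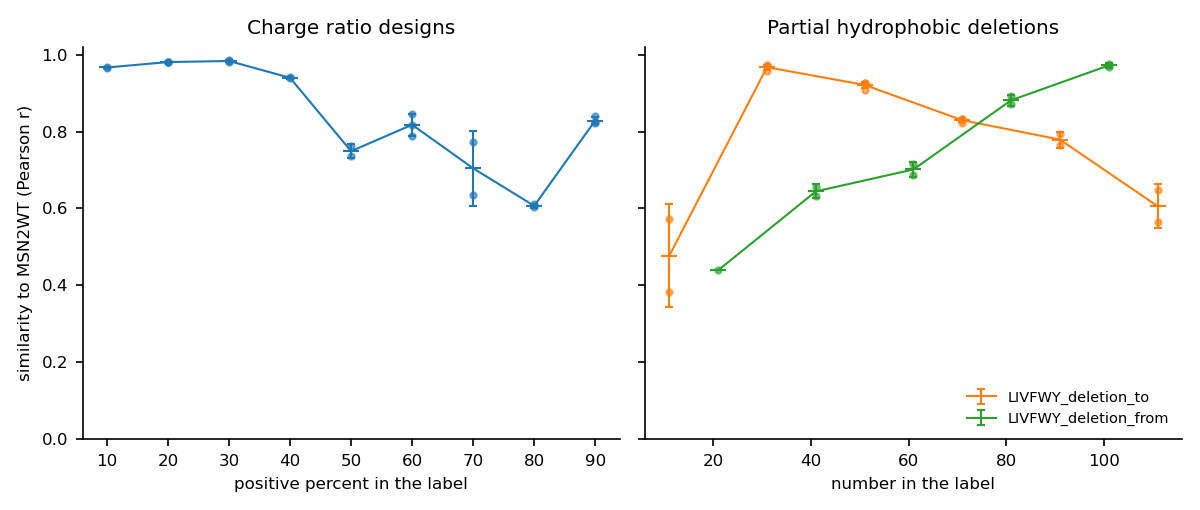
Similarity to MSN2WT (vertical axis, Pearson r, no unit) along the charge ratio designs (left, horizontal axis: positive percent in the label) and the partial hydrophobic deletions (right, horizontal axis: number in the label), with libraries as points and means with SD. Similarity is 0.967 at 10%, 0.607 at 80% and 0.829 at 90% positive residues, and 0.477 at LIVFWY_deletion_to11, 0.967 at LIVFWY_deletion_to31 and 0.606 at LIVFWY_deletion_to111.

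Partial hydrophobic deletions gave a range of similarities, with no linear trend over all 6 to designs. From LIVFWY_deletion_to31 on, similarity fell with the number in the label: 0.967 ± 0.0066 at to31, 0.921 ± 0.0082 at to51, 0.830 ± 0.0044 at to71 (SD, n = 4 each), 0.779 ± 0.021 at to91 and 0.606 ± 0.058 at to111 (SD, n = 2 each). The shortest design by its label, LIVFWY_deletion_to11, broke this order at 0.477 ± 0.134 (SD, n = 2). In the from series similarity was 0.439 in the single library of LIVFWY_deletion_from21 and 0.644, 0.702, 0.881 and 0.972 at from41, from61, from81 and from101. Over the 6 to designs Pearson r was -0.0038 (exact permutation p 0.997, adjusted 0.997). Without LIVFWY_deletion_to11, the design that broke the order, r was -0.970 (exact permutation p 0.0167, the smallest possible for the designs left). Because LIVFWY_deletion_to11 was singled out by its value, that p is no test of a trend. The libraries of LIVFWY_deletion_to11 held 58653 to 167930 promoter reads, fewer than any other library of the to series, while MSN2WT libraries thinned to their depth stayed at 0.983 or above.

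Designs with rearranged residues spread widely. Aliphatic residues gathered in clusters gave 0.123, 0.456 and 0.305 (LIV_cluster1, LIV_cluster2 and LIV_cluster3), and randomly placed ones 0.943, 0.965 and 0.892 (LIV_random1, LIV_random2 and LIV_random3). Acidic residues gave 0.230 in ED_shift1, 0.304 in ED_cluster2, 0.511 to 0.860 in the 3 random designs, 0.95 in DE_spread and 0.967 in ED_shift2. The 5 lowest of the 137 designs were LIV_cluster1, rep8x3 (0.129), FWY_cluster3 (0.224), ED_shift1 and rep8x2 (0.238), and the 5 highest PG_shift (0.985), 30p_70n_chargeratio, NS_swapped (0.983), 20p_80n_chargeratio and LIV_to_L. The planned comparison of aliphatic with acidic rearrangements, which pools clustered and random designs, gave 0.664 ± 0.359 and 0.647 ± 0.304 (SD, n = 7 each), a difference of 0.016 (exact permutation p 0.921, adjusted 0.997), and 0.067 (exact permutation p 0.718) within block 1.

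Designs labelled rep differed with x2 in the label, though the labels do not say what x2 and x3 stand for. Similarity was higher with x2 than without at 8 of 9 rep numbers, for example 0.577 and 0.810 for rep0 and rep0x2, and 0.573 and 0.825 for rep5 and rep5x2; rep8, the exception, stayed at 0.256 and 0.238. From x2 to x3 it rose at 6 of 10 rep numbers. The mean paired differences were 0.173 (exact sign-flip permutation p 0.00781, adjusted 0.0179; all in block 1; 0.0393 with the promoters beside the ribosomal RNA repeats kept) and 0.018 (exact sign-flip permutation p 0.607, adjusted 0.781), and 0.00095 over the 8 pairs within block 1 (exact permutation p 0.969). Asparagine designs ranged from 0.365 in N_to_Y to 0.962 in N_to_Q, and the designs with a residue changed beside asparagine from 0.346 in R_nextto_N to 0.956 in Q_nextto_N. Their means were 0.757 ± 0.221 and 0.690 ± 0.243 (SD, n = 8 each), with an exact permutation p of 0.558 (adjusted 0.781).

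**Figure D5:**
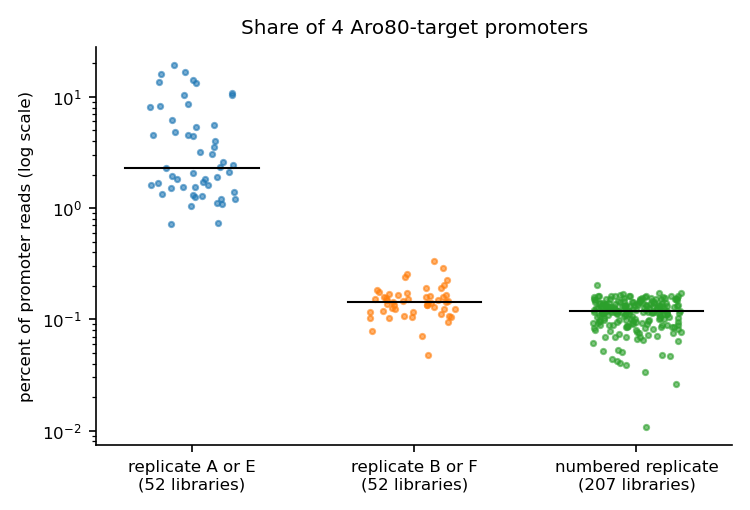
Percent of promoter reads (vertical axis, log scale) at 4 promoters of known Aro80 target genes in libraries of replicate letters A or E, B or F, and numbered replicates (horizontal axis). The medians are 2.31, 0.144 and 0.118%, and these 4 promoters are left out of every comparison.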

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

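Of the tests in this part, those of stray reads and of the amino acid change were chosen only after the result was seen. A strong signal sits where no comparison looks, at the promoters of 4 genes or gene pairs that the activator Aro80 is known to regulate: SDH6/ARO10, SPL2/ARO9, ESBP6/NAF1 and ARO80 itself. In the 52 libraries with replicate letter A or E they took a median of 2.31% of promoter reads (0.718 to 19.3%). The highest MSN2WT library had 0.118%, the B and F libraries a median of 0.144% and the numbered libraries a median of 0.118%. SDH6/ARO10 (chromosome IV, 1233518 to 1234217) held a median of 10478 RPM in A and E libraries and 305.2 ± 62.9 (SD, n = 5) in MSN2WT.

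The amino acid change of each design is argued against as the source, since the A or E library exceeded the B or F library of the same design in 52 of 52 pairs, by a median of 15.9-fold (2.84 to 337). A fixed number of stray reads per library would give a share that falls steeply with depth, and the Spearman rho of share with nuclear counts was only -0.201. A candidate explanation is that reads of another MNase fusion, with Aro80-like targets, are mixed into these libraries in varying amounts, but no value here decides for or against it. Log2 RPM at SDH6/ARO10 and SPL2/ARO9 correlated at 0.975 over the 52 libraries, as it would with any shared source of varying strength, since both promoters carry the signal and share a regulator. The design names no biological difference between letters, so no other biological explanation was tested.

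Single libraries stood far from their group in 3 of 42 tests (14 groups of 4 or 5 libraries, 3 measures each), and chance sets apart about 1 in 20. LIVFWY_deletion_to31 replicate 4 had a target share of 11.2% (95% counting interval 11.17 to 11.23%), next to 12.2% in the nearest library. LIVFWY_deletion_to51 replicate 2 had a similarity of 0.909, with the nearest at 0.925. MotAx3 replicate 3 had 29.9% of its nuclear reads in promoters (29.87 to 29.94%), with the nearest at 30.5%.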

How the results depend on the processing

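Keeping the promoters beside the ribosomal RNA repeats, keeping those of Aro80 targets, leaving out letters A and E and fitting shared replicate numbers without a block were chosen only after the data were seen; the other choices were made before the data were examined. Similarity and target share of LIVFWY_deletion, hydrophobic against polar substitutions and the charge series kept their direction and their side of the threshold under every alternative run, except that the target share difference was -10.8 percentage points against wt, with p 0.0667. The similarity difference of -0.426 became -0.210 on the log scale, -0.199 by rank and -0.237 with the promoters beside the ribosomal RNA repeats kept, where x2 against x1 became 0.0393 and hydrophobic against polar 0.0998. The to series turned to 0.151 on the log scale, 0.230 by rank and 0.147 with promoters of at most 400 bp, and ranged from -0.970 to 0.383 over leave-outs. The lowest value came without to11 (p 0.0167 by exact permutation), a design singled out by its value, so that p is no test of a trend. With libraries thinned to 200000 reads, where to11 drops out for depth, r was -0.972. X3 against x2 turned to -0.063 on the log scale and -0.067 by rank, with leave-outs from -0.0049 to 0.0369, and aliphatic against acidic to -0.0014 without letters A and E, with leave-outs from -0.0532 to 0.107. X2 against x1 was 0.210 in thinned libraries (exact p 1), where too few pairs remain for a test. Leave-outs gave 0.201 to 0.282 for hydrophobic against polar, -0.921 to -0.751 for the charge series and 0.163 to 0.196 for x2 against x1.

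Counts of called promoters depended on the reference and the scaling. With the 2 wt libraries as reference they fell to 1032 (511 lower, 521 higher) in LIVFWY_deletion, 292 (171, 121) in LIV_deletion, 158 (125, 33) in FWY_deletion, 278 (155, 123) in ED_deletion, 285 (124, 161) in NQ_deletion, 128 (30, 98) in ST_deletion, 292 (265, 27) in LIVFWY_to_A, 443 (69, 374) in 10p_90n_chargeratio and 190 (148, 42) in 90p_10n_chargeratio. By library size alone, which moves the median promoter from 0.12 to 0.25 with TMM to 0.56 to 2.10 over the 9 comparisons, the calls became 3191 (209, 2982) in LIV_deletion, 3182 (191, 2991) in FWY_deletion, 3287 (379, 2908) in ED_deletion, 3069 (219, 2850) in NQ_deletion, 1565 (89, 1476) in ST_deletion, 3325 (290, 3035) in LIVFWY_to_A, 1971 (50, 1921) in 10p_90n_chargeratio and 3206 (147, 3059) in 90p_10n_chargeratio. MSN2WT and wt together gave 2977 in LIVFWY_deletion, 2292 (351, 1941) in LIV_deletion, 2465 (368, 2097) in FWY_deletion, 2914 (515, 2399) in ED_deletion, 2606 (379, 2227) in NQ_deletion, 862 (222, 640) in ST_deletion, 2789 (479, 2310) in LIVFWY_to_A, 482 (259, 223) in 10p_90n_chargeratio and 2397 (301, 2096) in 90p_10n_chargeratio. With that joined reference the median promoter moved from 0.24 to 1.27 in LIVFWY_deletion (0.33 against wt alone). It moved from 0.16 to 0.93 in LIV_deletion (0.83 against wt alone), but only from 0.13 to 0.14 in ST_deletion. Where the median moved, the lower and higher counts depend on that shift. A replicate block, on the libraries with shared numbers, gave 2375 in LIVFWY_deletion (2372 without the block), 1685 in LIVFWY_to_A (1060 lower; 1848 without, 1070 lower), 866 in 10p_90n_chargeratio (843) and 1625 in 90p_10n_chargeratio (1630). Leaving out single libraries gave 2322 to 2388 in LIVFWY_deletion, 1227 to 1440 in LIV_deletion, 1683 to 2179 in FWY_deletion, 2304 to 2779 in ED_deletion, 2224 to 2320 in NQ_deletion, 1006 to 1257 in ST_deletion, 2030 to 2204 in LIVFWY_to_A, 572 to 800 in 10p_90n_chargeratio and 1541 to 1623 in 90p_10n_chargeratio. With 1 library left in an arm, it is assumed to vary like the other group. Camera with an estimated correlation called 0 of 108 list tests.

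Among named promoters called in the main fit, signs turned by library size alone at SSA4 in LIVFWY_deletion (0.74) and 90p_10n_chargeratio (0.33) and at TPS1/MEO1 (0.042) and HSP104 (0.062) in LIV_deletion, and against wt at TPS1/MEO1 (0.038) and HSP104 (0.30) in LIV_deletion, HXT5 in ST_deletion (0.16) and ALD3 in 10p_90n_chargeratio (0.080). Fold changes of named promoters kept their sign and side of the threshold in 308 of 312 cases with DESeq2 size factors, 245 of 312 by library size alone and 196 of 299 against wt; of those not called, 1, 13 and 11 turned sign. Mean similarities moved by over 1 SD in 89 designs by rank, 84 on the log scale, 86 with the promoters beside the ribosomal RNA repeats kept and 6 in thinned libraries. Unless stated, the cause was not tested. The motif preference was not run.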

Other observations

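Of the tests in this part, those of evenly spread reads, of the blocks, of designs with a raised target share and of both charge ends against each other were chosen only after the result was seen. A high share of reads at textbook targets and a wild-type-like profile came apart in some designs. Of 127 designs with at least 2 libraries, 9 had every library above every MSN2WT library in target share, where random order would give 5.14 on average, and 108 had every library below. LIVFWY_to_F reached 28.7 ± 0.40% (SD, n = 2) with a similarity of 0.839, and LIVFWY_to_Y 26.7 ± 1.87% (SD, n = 3) with a similarity of 0.682. In LIVFWY_to_Y the TSL1 promoter held 83848 ± 12854 RPM (SD, n = 3), 6.17-fold of MSN2WT, while CTT1 stood at 0.585-fold and HSP104 at 0.520-fold. Of the 13 promoters named in advance, 4 lay above and 6 below every MSN2WT library there. In LIVFWY_to_F the rise was broader, with 9 above (TSL1 3.77-fold, HXK1 3.44-fold) and only SSA4 below (0.608-fold). P_to_A (24.0 ± 3.69%; SD, n = 2) and S_to_A (22.9 ± 0.51%; SD, n = 2) also exceeded MSN2WT, as did charged_random_cluster_2, LIVFWY_to_V, ST_deletion, N_to_H and LIV_to_L.

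The low similarity of LIVFWY_deletion was weighed against lower depth, added background and a difference between the blocks. Lower depth would need thinned wild-type libraries to fall as far, but MSN2WT libraries thinned to the depth of each LIVFWY_deletion library stayed at 0.986 or above, and the highest LIVFWY_deletion library reached 0.613. An evenly spread background was argued against by promoters that rose past it: of 3551 promoters below the mean read density in every MSN2WT library, 69 lay above 2 times the mean in every LIVFWY_deletion library (70 in LIVFWY_to_A, 16 in ED_deletion and 0 in wt), for example FUS2, chosen after its values were seen, with a density of 5.4 ± 0.41 (SD, n = 4) against 0.360 ± 0.079 (SD, n = 5). The same wild-type profile diluted by an uneven background may still account for much of the loss, since 0% of the 200 promoters strongest in MSN2WT were called higher and 199 were called lower, a weak test because they were picked for a high wild-type level. The smaller share of nuclear reads in promoters and the larger mitochondrial share of LIVFWY_deletion, given in the last paragraph, would go with such a background. A difference between the blocks as the whole cause would need the block 2 wild type to fall as low, but the lowest wt library had 0.955 (on the log scale the wt libraries had 0.960 and, at 33156 promoter reads, 0.685, so that scale decides less), and in 25 of the 35 other designs of block 2 every library lay above the highest LIVFWY_deletion library. A true change of binding stays open.

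The low similarity of 70p_30n_chargeratio and 80p_20n_chargeratio is unlikely to come from depth alone, though their shallowest library held 6194 promoter reads: MSN2WT libraries thinned to the depth of these 4 libraries stayed at 0.959 or above, and the highest of the 4 reached 0.774.

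Regrouping the same samples tested whether chance could give as many called promoters in the 3 comparisons with at least 3 libraries per group. For LIVFWY_deletion 1 of 100 splits drawn, the real one, gave as many as 2360, and the highest other gave 1685. For LIVFWY_to_A it was 1 of 56 splits (2200, highest other 0) and for 90p_10n_chargeratio 1 of 56 (1619, highest other 15). The real split thus gave the most calls in all 3. Any other split mixes variant and MSN2WT libraries within a group, which widens the spread there and lowers the calls. Chance is therefore not excluded, since the real split can reach no less than 1 of 100 or 1 of 56. Replicates may also be technical.

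Designs outside the planned comparisons covered a wide range of similarity. Exchanges for alanine gave 0.980 ± 0.0033 for G_to_A, 0.977 ± 0.0066 for KR_to_A, 0.915 ± 0.0056 for L_to_A, 0.913 ± 0.0053 for S_to_A, 0.829 ± 0.0089 for P_to_A, 0.774 ± 0.030 for NQ_to_A and 0.255 ± 0.074 for DE_to_A (SD, n = 2 each). Acidic residues exchanged for glutamine (DE_to_Q, 0.958 ± 0.0073; SD, n = 2) and for asparagine (DE_to_N, 0.457 ± 0.023; SD, n = 3) lay far apart. Among designs labelled 90 the single library of 90_E_charged reached 0.976 and that of 90_D_charged 0.956, while 90_chargedaa_to_A had 0.394 ± 0.033 (SD, n = 2). Left_positive_right_negative had 0.840 ± 0.038 (SD, n = 2), MotAx3 0.836 ± 0.016 (SD, n = 4) and the single library of start_nls 0.367.

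Outside the tests, the mitochondrial share was 21.8 to 31.4% in LIVFWY_deletion libraries and 0.605 to 2.26% in MSN2WT, and the share of nuclear reads in promoters 23.5 ± 0.80% (SD, n = 4) and 50.0 ± 1.9% (SD, n = 5). LIVFWY_deletion and MSN2WT lie in separate blocks, so a block difference in these shares is not told apart from the deletion. Set directly against 90p_10n_chargeratio, 10p_90n_chargeratio differed at 816 of 4394 promoters in edgeR. Stress reporters were higher in 10p_90n_chargeratio at 14 of 30 promoters (median log2 fold change 0.97; p = 0.0811 with an estimated correlation), and hexose transport genes were lower at 8 and higher at 2 of 21 (median -0.42; p = 0.318 with an estimated correlation).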
